A study of Homo sapiens with 157 samples.

How the data were processed

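Expression was measured on 157 Affymetrix oligonucleotide arrays, 148 of tumours and 9 of normal fat, and groups were taken from the labels, which describe separate specimens. The table the authors deposited holds log2 values of 22283 probe sets, between 3.68 and 14.96, with no missing value. MAS5 and RMA are named per the submitters' processing notes, with no order or version. The log2 scale and an RMA-like normalization were inferred from the values, since array medians and quartiles are nearly equal (lower quartiles 5.45 to 5.71). The probe set definition and genome build are not given in the sources used here. No pair of arrays was a duplicate, as the highest correlation between arrays was 0.986.

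Of the probe sets, 19071 had 1 gene symbol in the platform annotation, 1043 had several and 2169 were not listed with a gene. Gene IDs of 19059 probe sets matched the GRCh38.p14 gene table, which was used for names and gene order only. Each gene was represented by the probe set of 1 symbol with the highest mean over all arrays. XIST and Y-linked genes (32) were left out. Genes whose highest group mean was under the 20th percentile of all values (5.30) were left out, which left 10759 of 11931 genes. FRS2 was not analysed here for lack of a probe set with a single symbol, nor NF1, whose probe set was below the filter. Some other genes of the fixed set are not reported here.

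A cell-means model of the 7 groups was fitted over all arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with Benjamini-Hochberg adjustment within each comparison. Comparisons were each subtype against FAT, each subtype against the unweighted mean of the other 5, and 6 pairs. Genes were called at an adjusted p under 0.05 and a log2 difference of at least 1. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The 30 lists were adipocyte, adipogenic regulators, fatty acid synthesis, mitochondrial oxidation, 12q13-q14 genes, 12q14-q15 genes, p53 target genes, cell cycle regulators and tumour suppressors, proliferation, smooth muscle, skeletal muscle, collagen and fibroblast matrix, myxoid matrix and hyaluronan, matrix metalloproteinases, receptor tyrosine kinases, growth factor ligands, cancer-testis genes, endothelial, T cell, B and plasma cell, macrophage, interferon response, MHC class I and II, hypoxia and glycolysis, immediate early and stress, positional homeobox and limb genes, erythrocyte, Schwann cell and nerve, keratinocyte and epithelial and mesothelial. In simulated data over 10759 genes, 100 were changed by 1.5 on the log2 scale and another 100 by 2.5. Recovery is given for the former. Noise was drawn independently for each gene, so the false calls do not cover genes that vary together on real arrays. In the design of DDLPS against FAT 94% were recovered with 1 false call, in that of PMFH against FAT 83% were recovered with 4 false calls, in that of PMFH against the other subtypes 95% were recovered with 8 false calls and in that of MFS against PMFH 87% were recovered with 5 false calls. In those of LMS against the other subtypes and of MFS against PLPS 99% were recovered with 0 false calls and 100% were recovered with 0 false calls. Groups, comparisons, lists and the alternatives were chosen before the data were examined, except where stated.

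Named genes were the 6 highest and 6 lowest called genes against FAT, the 10 highest and 5 lowest against the other subtypes, the 4 highest and 4 lowest in pairs, up to 4 called members per direction of a described list, and a fixed set (MDM2, CDK4, HMGA2, YEATS4, DDIT3, JUN, PPARG, ADIPOQ, MYH11, DES, RB1, CDKN2A, SKP2, MKI67, PRAME, RET and FGFR2, besides those not analysed or not reported). Not every gene the rule selects is printed. Tumours were assigned by leave-one-out nearest centroid with Pearson correlation on the 2000 most variable genes. Relations with CDK4 in DDLPS were planned over all arrays of the group, but the arrays fell into separate sets of CDK4 level, and the values are given within each set instead, a choice made after seeing the data. The set of few arrays had an exact permutation test. Other relations used 100000 permutations. Windows of 10 Mb were tested with Fisher's exact test over 10752 genes with a place in the gene table. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The assignment and window steps were tested on simulated data.

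Hybridisation and RNA controls were examined for unlabelled batches. K-means on a hybridisation control and the 18S signal gave a cluster of 35 arrays with all 9 FAT, 13 DDLPS, 7 MRCLPS and 6 PLPS. Alternatives covered the choice of probe set, the filter, normalization, the variance model, array weights, RNA quality, control clusters, skeletal muscle content, the samples in the model, the reference and each FAT and PMFH array left out. Blocks for the hybridisation-control and BioC clusters, the 18S signal and the ACTB 3 prime to 5 prime difference as covariates, fits within a cluster and fits without 8 arrays that stand apart from their group were added after seeing the data. The test of normal fat in the tumour pieces was run per array in several forms and, after these had been seen, on the mean linear signals of whole groups, with 95% intervals from 2000 bootstrap resamples of arrays.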

Results

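RNA from surgical specimens of soft-tissue sarcoma and of normal fat was measured on Affymetrix oligonucleotide arrays, 1 array per specimen. The tumours carried 6 diagnostic labels. Dedifferentiated liposarcoma (DDLPS) had 46 arrays, leiomyosarcoma (LMS) 26, myxofibrosarcoma (MFS) 30, pleomorphic malignant fibrous histiocytoma (PMFH) 3, myxoid and round cell liposarcoma (MRCLPS) 20 and pleomorphic liposarcoma (PLPS) 23. Normal fat (FAT) had 9. Array medians lay between 6.70 and 6.82 on the log2 scale, and the number of arrays in a group limits the precision of each value. Differences are log2 differences ± standard error from limma. That error rests on a variance for each gene that is shared by all 7 groups. Where a gene varied far more in a compared group than elsewhere, as TAC1 and SIM1 did in MRCLPS, the error is too small. A gene was called when its adjusted p was under 0.05 and its log2 difference was at least 1 in size. Levels are means ± SD. Counts of arrays give how many arrays of the group named first lay on the stated side of the reference level. Where the group on the lower side had a mean near or under the 20th percentile of all values (5.30), a difference is a lower bound in size and its rank is uncertain. Among the leading genes this held for TAC1, EMX2, PCP4 and RACGAP1 in FAT, LEP and SLC19A3 in the tumours, ADH1B in MRCLPS, ADIPOQ in DDLPS, LMS, MFS and PMFH, and TAC1 and SIM1 in the subtypes other than MRCLPS. It also held for MDM2 in the subtypes other than DDLPS.

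**Figure D1:**
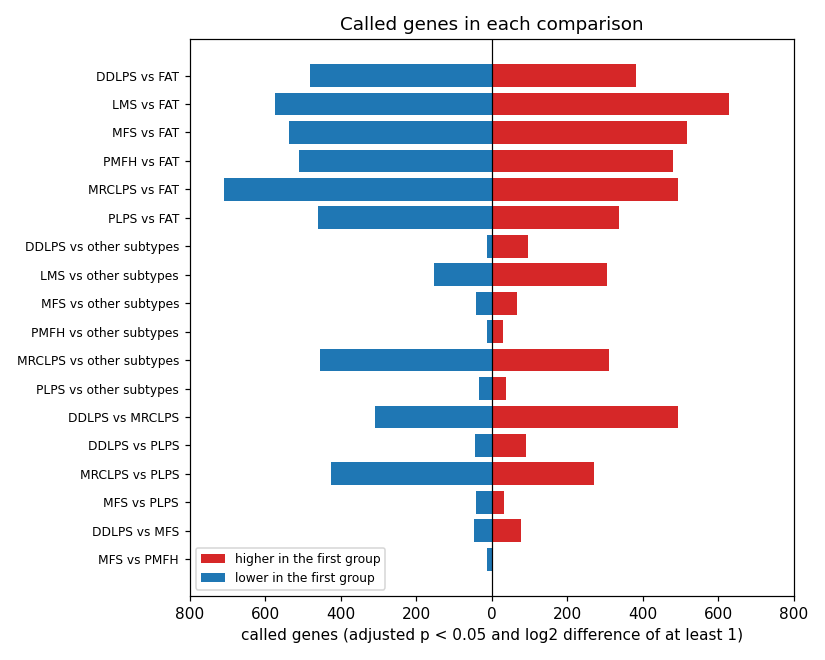
Bars show the number of called genes (x axis) in each comparison (y axis), those higher in the group named first to the right and those lower to the left. MRCLPS differed from the other subtypes at 766 genes and PMFH at 42.

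The comparisons with FAT asked how each tumour type differed from normal fat. Genes of mature fat cells were lower in each of the 6 subtypes. Of 22 adipocyte genes, the number lower was 19 in DDLPS, 19 in LMS, 19 in MFS, 19 in PMFH, 15 in MRCLPS and 19 in PLPS, with the same counts adjusted over the list alone. ADIPOQ, which encodes the hormone adiponectin, differed by -6.85 ± 0.46 (adjusted p = 2.27e-29, 46 of 46 arrays) in DDLPS and by -1.42 ± 0.50 (adjusted p = 0.0154, 20 of 20 arrays) in MRCLPS. LEP, the leptin gene, had a level of 10.09 ± 0.64 in FAT (n = 9) and group means between 4.86 and 5.32 in the tumours, so its differences are lower bounds in size. The adipocyte list was lower as a set in DDLPS (mean difference -3.91, 46 of 46 arrays, adjusted p = 5.78e-45) and in MRCLPS (mean difference -2.25, 20 of 20 arrays, adjusted p = 5.47e-16). With an estimated correlation the adjusted p was 2.61e-06 in DDLPS, 2.3e-05 in LMS, 2.56e-05 in MFS, 9.9e-06 in PMFH, 0.0179 in MRCLPS and 0.000467 in PLPS.

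Of 50 proliferation genes, the number higher was 35 in DDLPS, 41 in LMS, 43 in MFS, 41 in PMFH, 29 in MRCLPS and 41 in PLPS, with the same counts adjusted over the list alone. None were lower. The set test gave adjusted p = 9.15e-34 in MFS and adjusted p = 3.58e-10 in MRCLPS. With an estimated correlation the adjusted p was 0.0737 in DDLPS, 0.0631 in LMS, 0.0353 in MFS, 0.0837 in PMFH, 0.336 in MRCLPS and 0.0276 in PLPS. MKI67, a marker of cycling cells, differed by 1.23 ± 0.18 (adjusted p = 2.04e-09, 30 of 30 arrays) in MFS and by 0.36 ± 0.19 (adjusted p = 0.118, 18 of 20 arrays) in MRCLPS, where it was not called. Collagen and fibroblast matrix genes were higher in DDLPS (25 of 29 called, 25 adjusted over the list alone; adjusted p = 1.14e-11). With an estimated correlation the adjusted p was 0.0354 in DDLPS, 0.649 in LMS, 0.102 in MFS, 0.107 in PMFH, 0.949 in MRCLPS and 0.217 in PLPS. In MRCLPS 4 of 29 (4 adjusted over the list alone) were higher and 5 of 29 (5 adjusted over the list alone) were lower. The mean there was -0.05, the median 0.15 and the test upward. COL1A1, the main chain of type I collagen, differed by 3.93 ± 0.47 (adjusted p = 1.32e-12, 45 of 46 arrays) in DDLPS.

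Immediate early and stress genes, which cells switch on within minutes of a stimulus, were lower in all 6 subtypes, from 16 of 25 (16 adjusted over the list alone) in DDLPS to 23 of 25 (23 adjusted over the list alone) in MRCLPS. Examples in MRCLPS were KLF4 (-4.62 ± 0.46), FOS (-4.17 ± 0.52), FOSB (-4.15 ± 0.44) and JUNB (-3.56 ± 0.33). With an estimated correlation the adjusted p was 0.042 in DDLPS, 0.0316 in LMS, 0.0353 in MFS, 0.0253 in PMFH, 0.00875 in MRCLPS and 0.0463 in PLPS. JUN, a subunit of the AP-1 transcription factor, differed by -0.32 ± 0.24 (adjusted p = 0.306, 33 of 46 arrays) in DDLPS and was not called. Endothelial genes were lower in LMS (11 of 18 called, 11 adjusted over the list alone; adjusted p = 9.15e-09, and adjusted p = 0.0354 with an estimated correlation) and PLPS (8 of 18 called, 8 adjusted over the list alone; adjusted p = 1.01e-07, and adjusted p = 0.0528 with an estimated correlation). Fatty acid synthesis genes were lower in DDLPS (7 of 12 called, 7 adjusted over the list alone; adjusted p = 1.19e-08, and adjusted p = 0.00921 with an estimated correlation). Adipogenic regulators were lower there as well (8 of 22 called, 8 adjusted over the list alone; adjusted p = 0.000759, and adjusted p = 0.0354 with an estimated correlation). So were genes of mitochondrial oxidation (10 of 38 called, 10 adjusted over the list alone; adjusted p = 5.39e-15, and adjusted p = 0.0317 with an estimated correlation). At the preset correlation, the endothelial, fatty acid synthesis and adipogenic regulator lists passed in all 6 subtypes. The oxidation list passed in all but MRCLPS. The endothelial list mean was 8.52 in FAT and 7.23 (LMS) to 7.78 (MRCLPS) in the subtypes. That of fatty acid synthesis was 9.46 in FAT and 7.98 (LMS) to 8.47 (MRCLPS). In MRCLPS 1 of 38 (1 adjusted over the list alone) oxidation genes were lower (adjusted p = 0.366, and adjusted p = 0.868 with an estimated correlation, with mean -0.12, median 0.11 and test downward). The 18S ribosomal RNA signal was 12.03 ± 0.93 in FAT (n = 9), 9.09 ± 2.59 in DDLPS, 9.40 ± 2.72 in MRCLPS and 9.12 ± 2.26 in PLPS, where the highest arrays reached 13.06 to 13.89. It was 6.92 ± 0.70 in LMS, 7.26 ± 0.62 in MFS and 7.41 ± 0.75 in PMFH. The 3 prime to 5 prime difference of ACTB, a sign of RNA quality, was 0.43 in FAT and 0.66 to 1.31 in the subtype means.

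**Figure D2:**
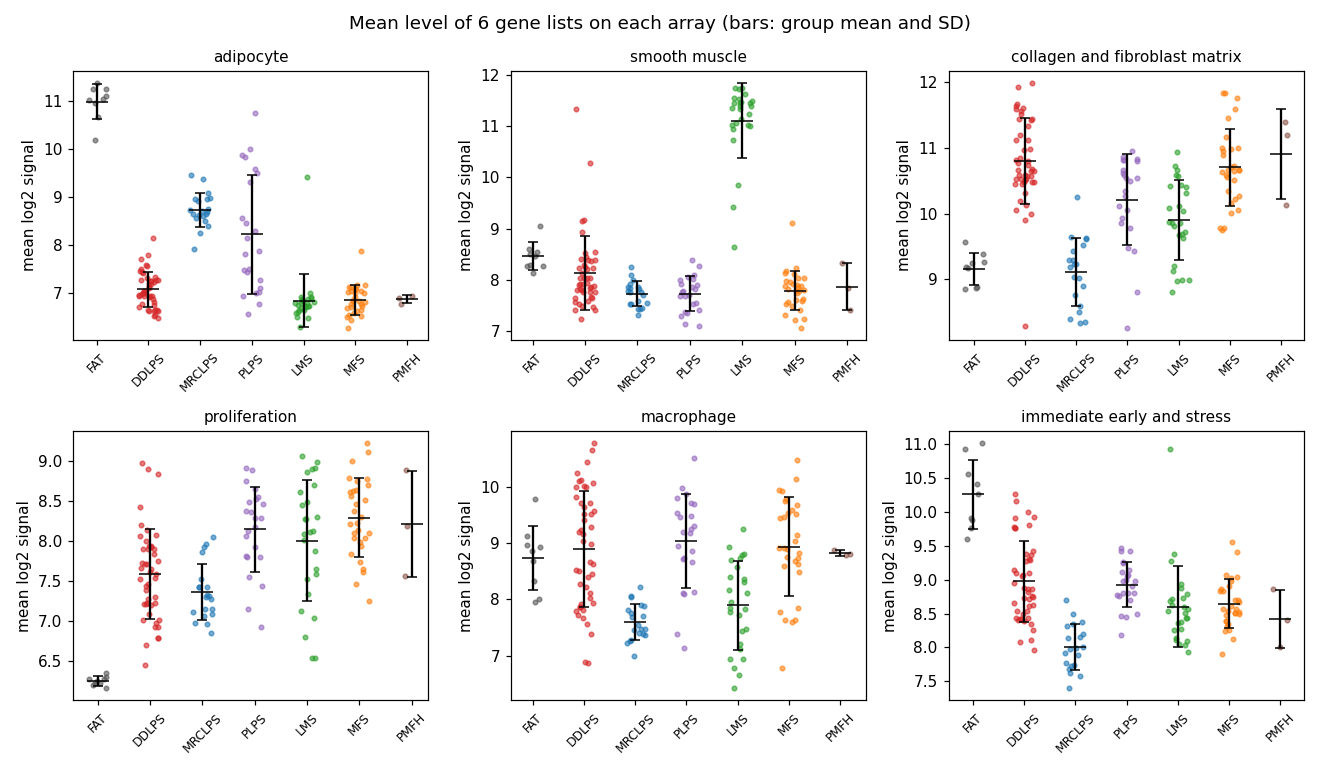
Each point is the mean log2 signal (y axis) of a gene list on 1 array, by group (x axis), with the group mean and SD as bars. The smooth muscle list was 3.26 higher in LMS than in the other subtypes and the adipocyte list 1.56 higher in MRCLPS.

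Several lists of cells that fat can hold differed little or through few members. Erythrocyte genes in DDLPS (adjusted p = 0.000117, and adjusted p = 0.0354 with an estimated correlation) were called lower at HBB (-4.34 ± 0.37), 1 of 5 (1 adjusted over the list alone). Mesothelial genes in LMS (adjusted p = 0.000445, and adjusted p = 0.0316 with an estimated correlation, with no pass for probe sets without cross-hybridisation suffixes) were called lower at CALB2 (-3.59 ± 0.19) and HP (-1.54 ± 0.34), 2 of 6 (2 adjusted over the list alone). Schwann cell and nerve genes in MFS (adjusted p = 0.00746, and adjusted p = 0.0353 with an estimated correlation) were called lower at S100B (-3.05 ± 0.11), 1 of 6 (1 adjusted over the list alone). None of this was particular to a subtype. At the preset correlation the erythrocyte, mesothelial and Schwann cell lists passed against FAT in all 6 subtypes. HBB, CALB2 and S100B were called lower in all 6. With only the 2 groups in the fit, the Schwann cell list passed in MFS alone. With probe sets without cross-hybridisation suffixes the mesothelial list passed in 0 of the 12 comparisons, from 6. The set test of keratinocyte and epithelial genes in DDLPS did not pass (adjusted p = 0.315, and adjusted p = 0.599 with an estimated correlation). Neither did that of skeletal muscle genes in LMS (adjusted p = 0.854, and adjusted p = 0.961 with an estimated correlation, with mean 0.14, median -0.02 and test upward) or of matrix metalloproteinases in MFS (adjusted p = 0.894, and adjusted p = 0.912 with an estimated correlation). Growth factor ligands were lower in LMS (7 of 26 called, 7 adjusted over the list alone; adjusted p = 0.0366, and adjusted p = 0.14 with an estimated correlation, with no pass in 5 of 26 other settings, among them those without FAT replicate 8 or 9). Positional homeobox and limb genes were higher in MFS, SHOX2 (2.35 ± 0.38), SIX2 (1.12 ± 0.28), HOXC6 (1.10 ± 0.35) and PRRX1 (1.07 ± 0.36) (4 of 30 called, 4 adjusted over the list alone; adjusted p = 0.0427, and adjusted p = 0.263 with an estimated correlation, with no pass in 9 of 26 other settings, among them those without FAT replicate 2, 4, 8 or 9). Interferon response genes were higher in PLPS, ISG15 (1.68 ± 0.45), CXCL10 (1.45 ± 0.45), IFI6 (1.44 ± 0.44) and IFI44 (1.42 ± 0.38) (4 of 24 called, 4 adjusted over the list alone; adjusted p = 0.0478, and adjusted p = 0.869 with an estimated correlation, with no pass in 12 of 27 other settings, among them those without FAT replicate 1, 2, 4, 5 or 8).

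DDLPS differed from FAT at 864 genes, 383 higher and 481 lower. The highest differences were in COL1A1 (3.93 ± 0.47), CDK4 (3.47 ± 0.28) and NREP (3.24 ± 0.32), followed by DLK1 (3.21 ± 0.90), CKS2 (3.17 ± 0.31) and TYMS (3.12 ± 0.34). CDK4 lay above every FAT array in 45 of 46 tumours. CKS2 and TYMS serve cell division and thymidylate synthesis. The lowest were in ADIPOQ (-6.85 ± 0.46), PLIN1 (-6.15 ± 0.40), RBP4 (-6.07 ± 0.64) and ADH1B (-6.03 ± 0.66). PLIN1 encodes a coat protein of fat droplets. LMS differed at 1202 genes, 627 higher and 575 lower, led by ACTG2 (5.84 ± 0.51), CNN1 (4.96 ± 0.38), PRUNE2 (4.51 ± 0.40), PCP4 (4.42 ± 0.44), MYH11 (4.29 ± 0.35) and KCNMB1 (4.26 ± 0.26), where ACTG2, CNN1, MYH11 and KCNMB1 serve smooth muscle contraction. MFS differed at 1054 genes, 516 higher and 538 lower, led by CKS2 (4.36 ± 0.33), COL1A1 (4.01 ± 0.49), NUSAP1 (3.96 ± 0.38), PCLAF (3.92 ± 0.35) and RACGAP1 (3.61 ± 0.25), which apart from COL1A1 serve replication and cell division.

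PMFH, with 3 arrays, differed from FAT at 991 genes, 481 higher and 510 lower, led by CKS2 (4.43 ± 0.57), MLLT11 (4.27 ± 0.78), COL1A1 (3.98 ± 0.85) and RRM2 (3.85 ± 0.60). MRCLPS differed at 1200 genes, 492 higher and 708 lower. Its highest differences were in SERPINE2 (5.16 ± 0.50), TAC1 (4.97 ± 0.38), SOX11 (4.94 ± 0.26), EMX2 (4.63 ± 0.35) and PRAME (4.62 ± 0.32). TAC1 encodes a neuropeptide precursor, SOX11 and EMX2 are developmental transcription factors, and PRAME is a cancer-testis antigen. Its lowest were in ADH1B (-6.92 ± 0.73), S100A8 (-5.26 ± 0.56), LEP (-5.10 ± 0.12) and SLC19A3 (-5.09 ± 0.16). PLPS differed at 796 genes, 337 higher and 459 lower, led by CKS2 (4.34 ± 0.34), NUSAP1 (3.59 ± 0.39), PCLAF (3.46 ± 0.36) and RACGAP1 (3.33 ± 0.26), and was lowest in LEP (-5.12 ± 0.11), ADIPOQ (-4.95 ± 0.49), SLC19A3 (-4.86 ± 0.15) and ADH1B (-4.82 ± 0.71). The LEP and SLC19A3 levels in MRCLPS (4.99 and 5.46) and PLPS (4.97 and 5.69) and those of TAC1 and EMX2 in FAT (4.32 and 5.08) were near or under the 20th percentile of all values. FAT replicate 8 stood apart in SERPINE2 and TAC1, and without it their differences in MRCLPS were 5.53 and 5.22. Hybridisation controls placed the FAT arrays in a technical cluster with part of the DDLPS, MRCLPS and PLPS arrays. Against tumours of that cluster alone, called genes kept a median 0.998 of their difference in DDLPS, 0.99 in MRCLPS and 1 in PLPS. With the cluster as a block it was 0.976 in LMS, 0.972 in MFS and 0.977 in PMFH, which had no array in it. With probe sets without cross-hybridisation suffixes, which tests fewer genes, the counts against FAT were 478 to 755.

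Across the 6 comparisons with FAT, 70 genes were called higher in all and 196 lower in all. CKS2 was among the former and ADIPOQ among the latter. Because the comparisons share the FAT arrays, overlap can arise without any effect. In 20 simulations of unchanged groups against the same arrays the highest shared counts were 0 higher and 0 lower. Unchanged groups give few calls, so this cannot show how much overlap the shared arrays add when tumours differ. Independent lists of these sizes would share 6.85e-05 and 0.000171 genes, but these lists share a reference, so that figure decides nothing either. With the FAT arrays split into sets of 5 and 4 for different subtypes, 55 and 154 genes were shared.

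The comparisons of each subtype with the mean of the other 5 asked what set it apart among the tumours. DDLPS was set apart by a group of genes of chromosome 12. MDM2, which encodes a ubiquitin ligase, was higher by 2.90 ± 0.19 (adjusted p = 6.01e-29, 43 of 46 arrays), and CDK4, a kinase of the G1 phase, by 2.72 ± 0.16 (adjusted p = 1.89e-33, 43 of 46 arrays). Mean MDM2 levels in the other subtypes were near the 20th percentile of all values. Its differences here and in the pairs below are therefore lower bounds in size. Of the 12q13-q14 list 11 of 28 (11 adjusted over the list alone) genes were higher, with none lower (adjusted p = 1.53e-32, and adjusted p = 3.75e-06 with an estimated correlation). Examples were EEF1AKMT3 (2.59 ± 0.15), TSPAN31 (2.51 ± 0.17) and METTL1 (2.32 ± 0.13). Of the 12q14-q15 list 7 of 23 (7 adjusted over the list alone) were higher (adjusted p = 3.36e-19, and adjusted p = 1.05e-07 with an estimated correlation). One was YEATS4 (1.28 ± 0.15), a chromatin reader. HMGA2, an architectural chromatin protein, differed by 0.84 ± 0.25 (adjusted p = 0.00621, 20 of 46 arrays) and was not called. Targets of p53 were higher as a set (mean difference 0.37, 42 of 46 arrays; adjusted p = 6.16e-08, and adjusted p = 0.003 with an estimated correlation), with 1 of 17 (1 adjusted over the list alone) called, ZMAT3.

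DDLPS was also higher in IGF2BP2 (2.45 ± 0.22), CCND2 (2.09 ± 0.24), CCND1 (2.02 ± 0.22) and COL11A1 (2.10 ± 0.41), where CCND1 and CCND2 are D-type cyclins, and lower in SLC6A8 (-1.48 ± 0.19), TMEM158 (-1.34 ± 0.29) and HPGD (-1.30 ± 0.23). Cell cycle regulators and tumour suppressors were higher as a set, with CCND2 (2.09 ± 0.24) and CCND1 (2.02 ± 0.22) (2 of 23 called, 2 adjusted over the list alone; adjusted p = 0.00119, and adjusted p = 0.00153 with an estimated correlation). RB1, the retinoblastoma gene, differed by 0.85 ± 0.13 (adjusted p = 1.07e-07, 40 of 46 arrays) and SKP2, a ligase subunit that promotes S phase, by -0.66 ± 0.13 (adjusted p = 3.64e-05, 42 of 46 arrays), neither called. B and plasma cell genes had 3 of 13 (3 adjusted over the list alone) higher, IGLC1 (1.60 ± 0.52), JCHAIN (1.20 ± 0.36) and IGKC (1.13 ± 0.40) (adjusted p = 0.003, and adjusted p = 0.369 with an estimated correlation). T cell genes had none called (mean difference 0.23, 26 of 46 arrays; adjusted p = 0.000443, and adjusted p = 0.472 with an estimated correlation). Receptor tyrosine kinases had 1 of 31 (1 adjusted over the list alone) higher, EPHA3 (1.75 ± 0.32) (adjusted p = 0.0461, and adjusted p = 0.271 with an estimated correlation, with no pass in 10 of 19 other settings). In all, 109 genes, 96 higher and 13 lower, were called.

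LMS was set apart by smooth muscle genes, of which 23 of 27 (23 adjusted over the list alone) were higher and none lower (mean difference 3.26, 26 of 26 arrays; adjusted p = 3.8e-72, and adjusted p = 2.8e-08 with an estimated correlation). Examples were CNN1 (5.92 ± 0.24), ACTG2 (5.53 ± 0.32), MYH11 (5.24 ± 0.22) and PLN (4.88 ± 0.31), which encode contractile proteins and their regulators. Single arrays overlapped. The smooth muscle list mean was 11.11 ± 0.74 in LMS, with 8.63 in LMS replicate 12, and 11.33 in DDLPS replicate 45. DES, the muscle intermediate filament desmin, was higher by 4.20 ± 0.29 (adjusted p = 4e-28, 25 of 26 arrays). RB1 differed by -0.73 ± 0.15 (adjusted p = 4.29e-05, 22 of 26 arrays) and was not called. Lower genes were led by MXRA5 (-2.56 ± 0.29), PTX3 (-2.54 ± 0.43), TNFAIP6 (-2.53 ± 0.35) and PLAGL1 (-2.51 ± 0.33). Macrophage genes were lower, among them CD14 (-1.29 ± 0.27), MS4A4A (-1.04 ± 0.34) and CD163 (-1.04 ± 0.28) (4 of 20 called, 4 adjusted over the list alone; adjusted p = 0.000199, and adjusted p = 0.687 with an estimated correlation). In all, 457 genes, 305 higher and 152 lower, were called.

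MFS was higher than the other subtypes in S100A4 (1.77 ± 0.27), IGFBP6 (1.77 ± 0.29), ADAMTS5 (1.65 ± 0.31) and LOXL1 (1.58 ± 0.25), where IGFBP6 binds insulin-like growth factors, ADAMTS5 cleaves proteoglycans and LOXL1 acts on elastin. KLF4, a transcription factor, was higher by 1.62 ± 0.26 (adjusted p = 1.07e-06, 28 of 30 arrays). Collagen and fibroblast matrix genes had 5 of 29 (5 adjusted over the list alone) higher (adjusted p = 1.95e-05, and adjusted p = 0.555 with an estimated correlation), and the list mean of 10.71 in MFS lay below 10.80 in DDLPS and 10.91 in PMFH. Hypoxia and glycolysis genes had none called (mean difference 0.25, 20 of 30 arrays; adjusted p = 0.00326, and adjusted p = 0.555 with an estimated correlation, with no pass for probe sets without cross-hybridisation suffixes). Adipocyte genes were lower (5 of 22 called, 5 adjusted over the list alone; adjusted p = 1.41e-07, and adjusted p = 0.416 with an estimated correlation), with LPL (-2.22 ± 0.29), FABP4 (-2.20 ± 0.48), ADIPOQ (-1.74 ± 0.29) and CD36 (-1.63 ± 0.33). The adipocyte list mean was 6.87 in MFS, 6.85 in LMS, 6.88 in PMFH and 7.08 in DDLPS, and the reference also held MRCLPS (8.74) and PLPS (8.23). In all, 108 genes, 67 higher and 41 lower, were called, and 171 with PMFH left out of the reference.

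PMFH was higher in MMP13 (2.93 ± 0.60), FMO1 (2.66 ± 0.66), MME (2.60 ± 0.50) and MLLT11 (2.54 ± 0.69), where MMP13 is a collagenase and MME a membrane peptidase, and lower in TMT1A (-1.95 ± 0.54), ISOC1 (-1.87 ± 0.49), TLE1 (-1.55 ± 0.40) and EHBP1 (-1.52 ± 0.37). Of the matrix metalloproteinases, 1 of 17 (4 adjusted over the list alone) was higher (adjusted p = 0.00379, and adjusted p = 0.29 with an estimated correlation, with no pass without PMFH replicate 1). In all, 42 genes, 30 higher and 12 lower, were called. The count was 27 without PMFH replicate 3, 70 with MFS left out of the reference, 26 with the poly-A control cluster as a block and 18 among arrays outside the technical cluster that held FAT.

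MRCLPS differed from the other subtypes at 766 genes, 310 higher and 456 lower. Fat cell genes were higher, with 11 of 22 (11 adjusted over the list alone) of the adipocyte list (mean difference 1.56, 20 of 20 arrays; adjusted p = 3.97e-07, and adjusted p = 0.347 with an estimated correlation). Examples were ADIPOQ (5.20 ± 0.33), FABP4 (5.13 ± 0.55), LPL (5.12 ± 0.33) and CD36 (4.94 ± 0.37). PPARG, the nuclear receptor that drives fat cell differentiation, was higher by 3.81 ± 0.25 (adjusted p = 2.11e-30, 20 of 20 arrays). A further group comprised TAC1 (5.15 ± 0.25), PEG3 (4.70 ± 0.30), PTX3 (4.52 ± 0.47), SIM1 (4.51 ± 0.11) and SOX11 (4.42 ± 0.17). PRAME was higher by 4.48 ± 0.21 (adjusted p = 1.74e-44, 20 of 20 arrays), with 2 of 12 (2 adjusted over the list alone) of the cancer-testis genes, PRAME (4.48 ± 0.21) and CTAG2 (3.52 ± 0.15) (adjusted p = 0.0201, and adjusted p = 0.391 with an estimated correlation, with no pass with no dim filter). RET and FGFR2, receptor tyrosine kinases, were higher by 1.22 ± 0.07 and 2.38 ± 0.27. DDIT3, a transcription factor of the stress response, differed by 0.47 ± 0.23 (adjusted p = 0.0871, 19 of 20 arrays) and was not called.

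In MRCLPS, the collagen and fibroblast matrix list had 15 of 29 (15 adjusted over the list alone) lower (adjusted p = 3.4e-08, and adjusted p = 0.347 with an estimated correlation), with COL1A2 (-3.75 ± 0.26) and LUM (-3.69 ± 0.41) as examples. The macrophage list had 13 of 20 (13 adjusted over the list alone) lower (adjusted p = 1.41e-06, and adjusted p = 0.391 with an estimated correlation). The MHC class I and II list had 3 of 15 (3 adjusted over the list alone) lower, CD74 (-1.18 ± 0.26), HLA-DQB1 (-1.07 ± 0.25) and HLA-DMA (-1.03 ± 0.26) (adjusted p = 0.00107, and adjusted p = 0.507 with an estimated correlation, with no pass for probe sets without cross-hybridisation suffixes). The myxoid matrix and hyaluronan list had 1 of 18 (1 adjusted over the list alone) higher and 3 of 18 (3 adjusted over the list alone) lower (adjusted p = 0.0935, and adjusted p = 0.391 with an estimated correlation). CDKN2A, which encodes an inhibitor of CDK4, differed by -1.78 ± 0.26 (adjusted p = 1.6e-09, 20 of 20 arrays).

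PLPS was higher than the other subtypes in CFD (2.48 ± 0.40), C3 (2.31 ± 0.46), CD36 (2.03 ± 0.35), FABP4 (1.86 ± 0.52) and APOE (1.64 ± 0.23), where CFD and C3 belong to complement, CD36 and FABP4 bind fatty acids and APOE carries lipids. The adipocyte list had 10 of 22 (10 adjusted over the list alone) higher and none lower (mean difference 0.94, 16 of 23 arrays; adjusted p = 1.6e-17, and adjusted p = 0.0143 with an estimated correlation). PLPS arrays were mixed, with a list mean of 8.23 ± 1.23, from 6.57 in replicate 15 to 10.76 in replicate 23. The mean was 7.08 ± 0.37 in DDLPS, so the higher level belonged to part of the PLPS arrays. Smooth muscle genes had 13 of 27 (13 adjusted over the list alone) lower (adjusted p = 1.46e-19, and adjusted p = 0.0143 with an estimated correlation), with ACTG2 (-1.65 ± 0.33), CNN1 (-1.47 ± 0.25) and MYH11 (-1.24 ± 0.23). The smooth muscle list mean was 7.72 in PLPS, 7.73 in MRCLPS, 7.79 in MFS, 7.86 in PMFH and 8.13 in DDLPS, and the reference also held LMS (11.11). In all, 70 genes, 37 higher and 33 lower, were called.

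Pairs of subtypes were compared directly. DDLPS was higher than MRCLPS in matrix genes, LUM (4.59 ± 0.41), COL1A2 (4.09 ± 0.27) and COL1A1 (3.64 ± 0.34). It was lower in ADIPOQ (-5.43 ± 0.34), LPL (-5.19 ± 0.33), TAC1 (-5.17 ± 0.26) and FABP4 (-4.62 ± 0.56), and in all 800 genes, 492 higher and 308 lower, were called. Against PLPS it was higher in MDM2 (2.80 ± 0.24), EEF1AKMT3 (2.78 ± 0.19) and CDK4 (2.75 ± 0.20) and lower in RBP4 (-2.60 ± 0.45), LPL (-2.09 ± 0.32) and CD36 (-2.05 ± 0.36). In all 134 genes, 90 higher and 44 lower, were called, and 250 genes among the arrays that shared a technical cluster with FAT. MRCLPS was higher than PLPS in TAC1 (5.23 ± 0.29), PEG3 (4.71 ± 0.35) and SOX11 (4.53 ± 0.20) and lower in C3 (-3.92 ± 0.57), CLU (-3.43 ± 0.45) and COL1A2 (-3.29 ± 0.30), with 699 genes, 272 higher and 427 lower.

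MFS was higher than PLPS in IGFBP6 (1.71 ± 0.35) and AHNAK2 (1.62 ± 0.35) and lower in FABP4 (-3.38 ± 0.58), CD36 (-3.05 ± 0.39) and LPL (-3.02 ± 0.34). In all 73 genes, 32 higher and 41 lower, were called, and 36 genes among the arrays outside that cluster. DDLPS was higher than MFS in MDM2 (2.89 ± 0.22), CDK4 (2.69 ± 0.18) and TSPAN31 (2.66 ± 0.19) and lower in SPP1 (-1.76 ± 0.42), S100A4 (-1.52 ± 0.28) and CCNB1 (-1.52 ± 0.20), with 125 genes, 77 higher and 48 lower. MFS and PMFH differed at 13 genes, 0 higher and 13 lower, with FMO1 (-2.75 ± 0.68) and MME (-2.21 ± 0.52) the lowest, and 21 of 100 splits of the same arrays, the real one included, gave as many genes. Without PMFH replicate 1 the count was 40, without PMFH replicate 3 it was 29, and with only these groups in the model it was 4.

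MDM2 and CDK4 were both above every FAT array in 43 of 46 DDLPS arrays, and in 6 of 20 MRCLPS, 5 of 30 MFS, 4 of 23 PLPS, 3 of 26 LMS and 0 of 3 PMFH. The highest FAT levels were 5.65 for MDM2 and 9.69 for CDK4. The highest MDM2 level was 11.68 in DDLPS, 7.42 in MFS, 6.2 in MRCLPS and 6.18 in LMS. The highest CDK4 level was 13.75 in DDLPS, 10.97 in MFS, 10.53 in MRCLPS and 10.61 in LMS. The highest CDK4 level of all arrays, picked after seeing the values, was 14.18 in PLPS replicate 14, whose MDM2 level was 9.55. CDK4 levels in DDLPS fell into a set of 40 arrays and a set of 6 lower ones with a gap of 1.03 between them, so relations with CDK4 are given within each set, adjusted over 4 tests, all two-sided. For MDM2 and CDK4 in the higher set, Pearson r was 0.421 (permutation p = 0.00581, adjusted 0.0232) and Spearman rho 0.348 (permutation p = 0.027, adjusted 0.108). Without the 2 arrays farthest from the median r was 0.444. It was 0.311 in the 12 arrays of the technical cluster that held FAT and 0.45 in the other 28. In the lower set, Pearson r was 0.548 (exact permutation p = 0.278, adjusted 0.36) and Spearman rho 0.257 (exact permutation p = 0.658, adjusted 0.658). For the 12q14-q15 list mean and CDK4 in the higher set, Pearson r was 0.247 (permutation p = 0.125, adjusted 0.251) and Spearman rho 0.292 (permutation p = 0.0686, adjusted 0.137). Without the 2 arrays farthest from the median r was 0.264. It was -0.134 in the 12 arrays of the technical cluster that held FAT and 0.467 in the other 28. In the lower set, Pearson r was 0.469 (exact permutation p = 0.36, adjusted 0.36) and Spearman rho 0.657 (exact permutation p = 0.175, adjusted 0.233). Among these, the adjusted p was under 0.05 for Pearson r of MDM2 and CDK4 in the higher set and for no rho. In the planned permutation tests over all 46 DDLPS arrays, adjusted over 6 tests, both relations were positive and passed. The adjusted p for Pearson and Spearman was 6e-05 and 0.00366 for MDM2 and CDK4. It was 0.00048 and 0.0133 for the list and CDK4. Those tests include the gap between the sets. A cut on CDK4 narrows its range and can lower r within a set. The lower set had too few arrays in each technical cluster for a value.

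The other relations belonged to a planned family of 6 and were tested with two-sided permutation tests adjusted over it. The adipocyte and proliferation list means were not related past the threshold in DDLPS, MRCLPS or PLPS. In DDLPS, Pearson r was -0.249 over 46 arrays (permutation p = 0.0951, adjusted 0.19). Spearman rho was -0.203 (permutation p = 0.173, adjusted 0.345). Without the 2 arrays farthest from the median r was -0.169. It was 0.229 in the 13 arrays of the technical cluster that held FAT and -0.43 in the other 33. In MRCLPS, Pearson r was -0.157 over 20 arrays (permutation p = 0.509, adjusted 0.553). Spearman rho was -0.212 (permutation p = 0.365, adjusted 0.438). Without the 2 arrays farthest from the median r was -0.153. It was -0.236 in the 7 arrays of the technical cluster that held FAT and -0.177 in the other 13. In PLPS, Pearson r was -0.13 over 23 arrays (permutation p = 0.553, adjusted 0.553). Spearman rho was -0.25 (permutation p = 0.251, adjusted 0.376). Without the 2 arrays farthest from the median r was -0.155. It was 0.168 in the 6 arrays of the technical cluster that held FAT and -0.204 in the other 17. For MDM2 and the adipocyte list in DDLPS, Pearson r was 0.154 over 46 arrays (permutation p = 0.308, adjusted 0.463). Spearman rho was 0.063 (permutation p = 0.678, adjusted 0.678). Without the 2 arrays farthest from the median r was 0.075. It was -0.146 in the 13 arrays of the technical cluster that held FAT and 0.224 in the other 33.

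**Figure D3:**
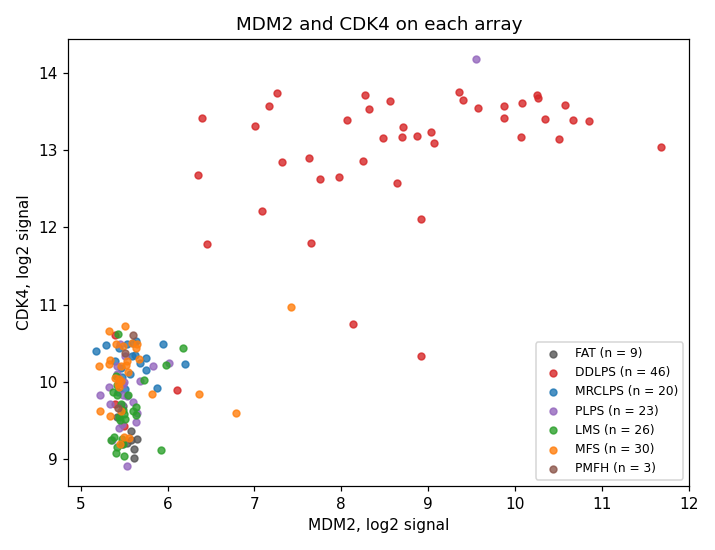
Each point is 1 array, with the log2 signal of MDM2 on the x axis and of CDK4 on the y axis, coloured by group. In 43 of 46 DDLPS arrays, and in 6 MRCLPS, 5 MFS, 4 PLPS and 3 LMS arrays, both genes lay above all 9 FAT arrays. The highest MDM2 level was 5.65 in FAT, 11.68 in DDLPS, 9.55 in PLPS, 7.42 in MFS, 6.2 in MRCLPS and 6.18 in LMS.

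Called genes were set against gene order in windows of 10 Mb with Fisher's exact test. The test counts neighbouring members of a gene family as separate genes, so a window can pass through a single family. In DDLPS, higher genes were concentrated in 3 windows. The window from MON2 to CCT2 (8 of 26 genes, 30.8% against 0.89% of all genes, adjusted p = 1.25e-08) held MDM2 and YEATS4. CDK4 lay in the window from ASIC1 to SLC16A7 (10 of 137 genes, 7.3% against 0.89% of all genes, adjusted p = 5.5e-05). The other ran from KERA to APAF1 (4 of 21 genes, 19% against 0.89% of all genes, adjusted p = 0.00323). The genes called there were LUM, DCN, PLXNC1 and ELK3. LUM was 4.59 ± 0.41 higher in DDLPS than in MRCLPS, which was part of the reference. In LMS, higher genes were concentrated from LINC02249 to GPR176 (5 of 22 genes, 22.7% against 2.84% of all genes, adjusted p = 0.0499) and from TNMD to ACSL4 (7 of 47 genes, 14.9% against 2.84% of all genes, adjusted p = 0.0499). The 7 genes of the latter included TCEAL1, TCEAL2 and TCEAL4. Lower genes were concentrated from COXFA4 to TWIST1 (4 of 15 genes, 26.7% against 1.41% of all genes, adjusted p = 0.0142). In PLPS, higher genes were concentrated from TPD52 to NBN (3 of 16 genes, 18.8% against 0.34% of all genes, adjusted p = 0.00621) and from ZMYND11 to GATA3 (3 of 28 genes, 10.7% against 0.34% of all genes, adjusted p = 0.0177). The genes called were FABP5, FABP4 and CA3 in the former and AKR1C1, AKR1C2 and AKR1C3 in the latter. Lower genes were concentrated from LINC02249 to GPR176 (4 of 22 genes, 18.2% against 0.31% of all genes, adjusted p = 0.000158). All 4 were among the 5 called higher in LMS there, and LMS was part of the reference for PLPS. With windows of 5 Mb, no passing window held any called gene of the 2 windows higher in LMS or of the 2 higher in PLPS. With windows of 20 Mb, none held any from LINC02249 higher in LMS, from COXFA4 lower in LMS, or of the 2 windows higher in PLPS. No window passed in the comparisons of MFS, PMFH and MRCLPS with the other subtypes.

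Each tumour was also set against the mean profile of every label, computed without it. In 116 of the tumours (78.4%) the nearest profile was that of its own label, against at most 51 under 100 permutations of the labels. All 20 MRCLPS and 24 of 26 LMS were nearest to their own label, as were 37 of 46 DDLPS, 22 of 30 MFS and 13 of 23 PLPS. Of the other PLPS, 7 were nearest to MFS. The 3 PMFH were all nearest to MFS, and 4 MFS were nearest to PMFH.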

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

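The tests of normal fat in the tumour pieces were chosen after the adipocyte values had been seen, the one over whole groups after those per array, and the fits within or blocked for the technical cluster or with the ACTB covariate were chosen after seeing the data.

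Among the 9 FAT arrays, 21 of 146 measures had 1 array far from the rest, and chance alone gives about 1 in 20. The gap to the nearest array, as a share of the range, was above Dixon's bound for adipogenic regulators list mean in FAT replicate 8 (0.496), cell cycle regulators and tumour suppressors list mean in FAT replicate 8 (0.558), smooth muscle list mean in FAT replicate 3 (0.502), hypoxia and glycolysis list mean in FAT replicate 8 (0.769), erythrocyte list mean in FAT replicate 9 (0.53), the median correlation with the other arrays of the group in FAT replicate 8 (0.744), ACTG2 in FAT replicate 3 (0.589), CCT2 in FAT replicate 8 (0.727), CKS2 in FAT replicate 8 (0.499), DES in FAT replicate 3 (0.553), IGF2BP2 in FAT replicate 8 (0.548), ISG15 in FAT replicate 3 (0.519), LUM in FAT replicate 9 (0.505), METTL1 in FAT replicate 8 (0.815), PLIN1 in FAT replicate 8 (0.697), RB1 in FAT replicate 4 (0.514), SERPINE2 in FAT replicate 8 (0.839), TAC1 in FAT replicate 8 (0.855), TMT1A in FAT replicate 8 (0.681), TNFAIP6 in FAT replicate 8 (0.507) and TSPAN31 in FAT replicate 8 (0.591). With each FAT array left out in turn, the counts of called genes against FAT ranged over 843 to 882 in DDLPS (882 without FAT replicate 8), 1189 to 1224 in LMS (1224 without FAT replicate 8), 1036 to 1095 in MFS (1095 without FAT replicate 8), 942 to 1012 in PMFH (1012 without FAT replicate 8), 1166 to 1229 in MRCLPS (1211 without FAT replicate 8) and 772 to 809 in PLPS (809 without FAT replicate 8).

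Relative to FAT, some genes were called higher in 1 subtype and lower in another, and limma's test of the difference between the subtypes passed for each named here. Since they were picked for opposite calls in the same data, that test adds no independent support. The log2 differences between the subtypes were CNN1 (LMS over MRCLPS, 6.24), MYH11 (LMS over PLPS, 5.40), IGF2BP2 (DDLPS over MRCLPS, 3.37), PLN (LMS over MRCLPS, 5.13), PTX3 (MRCLPS over LMS, 5.89), PLAGL1 (DDLPS over LMS, 2.97), AHNAK2 (LMS over MRCLPS, 3.93), ISOC1 (MRCLPS over PMFH, 4.03), EHBP1 (MRCLPS over PMFH, 2.85), PEG3 (MRCLPS over MFS, 5.13), COL1A2 (PMFH over MRCLPS, 4.21), LUM (DDLPS over MRCLPS, 4.59), PRRX1 (MFS over MRCLPS, 2.12) and smooth muscle (LMS over PLPS, 3.38), where smooth muscle is the list mean.

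Probe sets with no gene name here, which the comparisons do not use, also differed. Of 1464 such probe sets, up to 62 were higher than in FAT in a subtype, the most in MRCLPS, and 2 were higher and 17 lower in all 6.

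The many differences between tumours and FAT might come from the technical cluster that holds every FAT array. Within that cluster the called genes of DDLPS, MRCLPS and PLPS kept at least 0.99 of their differences on median. With the cluster as a block, those of LMS, MFS and PMFH kept at least 0.972. The values within the cluster argue against it as the cause in DDLPS, MRCLPS and PLPS. LMS, MFS and PMFH have no array in the cluster, so their values hold only if the cluster effect seen in the other subtypes carries over. Differences in tissue and handling between fat and tumour pieces stay open and were not tested.

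High adipocyte genes in MRCLPS and PLPS might come from normal fat in the pieces, tested by setting 9 other genes high in FAT (GHR, GYG2, PPP1R1A, PRKAR2B, SLC19A3, TIMP4, FOSB, HBB and S100A8, the last 3 not specific to fat cells) against the level that the share of fat implied by the adipocyte genes predicts. In MRCLPS (median implied share 10.7%) they lay on median -1.56 log2 units from that level, and over 1 unit below it in 17 of 20 arrays, which argues against fat as the whole source. In PLPS 13 of 23 arrays implied 5% fat or less and could show little shortfall, so that test (median -0.344, within the bound first set for fat as the cause) decides nothing there, nor do forms that pick arrays or genes by measured values (-2.58, -2.33 and -0.37 in PLPS, -1.59, -1.70 and -1.43 in MRCLPS). Over the whole group, the mean signals of PLPS implied 17.1% fat from the adipocyte list and 3.47% from the other genes, a log2 ratio of -2.30 (bootstrap interval -3.39 to -1.47), or -1.61 (bootstrap interval -2.48 to -1.11) without FOSB, HBB and S100A8, which argues against fat as the whole source there too, and the ratio in MRCLPS was -3.50 (bootstrap interval -6.98 to -2.54). Means of linear signals weigh most the arrays with high levels, and the median PLPS array implied 3.2% fat. The value for the whole PLPS group therefore speaks mainly for its arrays with high adipocyte levels. Fat as part of the source stays open, and a fat-like state of the tumour cells was not tested.

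Lower immediate early genes in the tumours might come from the technical cluster or from RNA degradation. Within the cluster that holds FAT the list difference of DDLPS, MRCLPS and PLPS was at least 0.861 of that over all arrays. This argues against the cluster as the whole cause in these subtypes. With the cluster as a block, the list difference of LMS, MFS and PMFH was at least 0.988 of that without it. They have no array in the cluster, so their value holds only if the cluster effect seen in the other subtypes carries over. The 3 prime to 5 prime difference of GAPDH in FAT (0.84) lay within the group means of the tumours (0.70 to 0.98), so the fit with it as a covariate, where at least 0.97 of the list difference stayed, decides nothing. That of ACTB was lower in FAT (0.43) than in the tumours (0.66 to 1.31), and with it as a covariate the list difference was at least 1.02 of that without, which argues against a linear trend with ACTB as the whole cause. Degradation that ACTB does not measure and the time from surgery to freezing, which was not given in the sources used here, stay open.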

How the results depend on the processing

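The blocks for the hybridisation-control and BioC clusters, the 18S and ACTB covariates, the fits within a cluster and the fits without arrays that stand apart were chosen after seeing the data.

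Of 403 recomputed counts of genes, assignments, relations, windows and shared genes, 375 stayed within 1.5 times and 28 did not. The number of called genes moved as follows. With probe sets without cross-hybridisation suffixes, the counts were DDLPS vs FAT 530 (from 864), LMS vs FAT 755 (from 1202), MFS vs FAT 634 (from 1054), PMFH vs FAT 597 (from 991), MRCLPS vs FAT 754 (from 1200), PLPS vs FAT 478 (from 796), DDLPS vs other subtypes 65 (from 109), LMS vs other subtypes 280 (from 457), MFS vs other subtypes 53 (from 108), MRCLPS vs other subtypes 465 (from 766), PLPS vs other subtypes 34 (from 70), DDLPS vs MRCLPS 505 (from 800), DDLPS vs PLPS 76 (from 134), MRCLPS vs PLPS 423 (from 699), MFS vs PLPS 36 (from 73), DDLPS vs MFS 75 (from 125), MFS vs PMFH 6 (from 13). With a reference without PMFH (for PMFH, without MFS), the counts were MFS vs other subtypes 171 (from 108), PMFH vs other subtypes 70 (from 42). With a poly-A control cluster as a block, the counts were PMFH vs other subtypes 26 (from 42), MFS vs PMFH 6 (from 13). Among arrays within the other cluster, the counts were PMFH vs other subtypes 18 (from 42), MFS vs PLPS 36 (from 73). Among arrays within the cluster that holds FAT, the counts were DDLPS vs PLPS 250 (from 134). With only the 2 groups in the fit, the counts were MFS vs PMFH 4 (from 13). With 1 PMFH or FAT array left out, counts ranged over 27 to 63 for PMFH vs other subtypes, 17 to 40 for MFS vs PMFH. The lowest for PMFH vs other subtypes was without PMFH replicate 3 (27), and for MFS vs PMFH the highest were without PMFH replicate 1 (40) and replicate 3 (29). Leaving out probe sets with suffixes tests fewer genes. For the other settings the cause was not tested.

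Each list was scored by the number of the 12 comparisons in which it passed. Of 1020 recomputed numbers 937 stayed within 1.5 times. With estimated correlation: adipocyte 7 (from 12), adipogenic regulators 5 (from 8), mitochondrial oxidation 1 (from 10), 12q13-q14 genes 2 (from 4), proliferation 2 (from 11), smooth muscle 3 (from 11), skeletal muscle 0 (from 1), collagen and fibroblast matrix 1 (from 10), myxoid matrix and hyaluronan 0 (from 1), matrix metalloproteinases 0 (from 3), receptor tyrosine kinases 0 (from 1), growth factor ligands 0 (from 2), cancer-testis genes 0 (from 3), endothelial 1 (from 7), T cell 0 (from 2), B and plasma cell 0 (from 1), macrophage 0 (from 7), interferon response 0 (from 2), MHC class I and II 0 (from 4), hypoxia and glycolysis 0 (from 5), positional homeobox and limb genes 0 (from 3), Schwann cell and nerve 2 (from 6). With probe sets without cross-hybridisation suffixes: 12q13-q14 genes 2 (from 4), cell cycle regulators and tumour suppressors 2 (from 1), smooth muscle 7 (from 11), skeletal muscle 0 (from 1), myxoid matrix and hyaluronan 0 (from 1), receptor tyrosine kinases 0 (from 1), growth factor ligands 0 (from 2), MHC class I and II 0 (from 4), hypoxia and glycolysis 1 (from 5), mesothelial 0 (from 6). With a sample-weighted reference: 12q14-q15 genes 5 (from 3), p53 target genes 2 (from 1), skeletal muscle 2 (from 1). With array weights: p53 target genes 2 (from 1), receptor tyrosine kinases 0 (from 1), positional homeobox and limb genes 1 (from 3), Schwann cell and nerve 3 (from 6). Among arrays within the cluster that holds FAT: p53 target genes 2 (from 1), Schwann cell and nerve 3 (from 6). With a skeletal muscle list covariate: skeletal muscle 0 (from 1). Among arrays within the other cluster: skeletal muscle 2 (from 1), receptor tyrosine kinases 0 (from 1). With mean of all probe sets: receptor tyrosine kinases 0 (from 1), growth factor ligands 1 (from 2). With no dim filter: receptor tyrosine kinases 0 (from 1), growth factor ligands 1 (from 2), cancer-testis genes 0 (from 3), positional homeobox and limb genes 1 (from 3). With GAPDH 3 prime to 5 prime covariate: receptor tyrosine kinases 0 (from 1), interferon response 1 (from 2). With a poly-A control cluster as a block: receptor tyrosine kinases 0 (from 1), interferon response 1 (from 2). With hybridisation-control cluster as a block: receptor tyrosine kinases 0 (from 1), positional homeobox and limb genes 5 (from 3). With 18S signal covariate: receptor tyrosine kinases 0 (from 1), interferon response 5 (from 2). With BioC control cluster as a block: receptor tyrosine kinases 0 (from 1). With 40th percentile filter: interferon response 1 (from 2). With values quantile normalized: interferon response 1 (from 2). With values median centred: interferon response 1 (from 2). With ACTB 3 prime to 5 prime covariate: interferon response 1 (from 2). Without the arrays that stand apart: positional homeobox and limb genes 0 (from 3). With only the 2 groups in the fit: Schwann cell and nerve 1 (from 6). With 1 FAT or PMFH array left out, the numbers ranged over 1 to 2 for p53 target genes (from 1), 1 to 2 for growth factor ligands (from 2), 1 to 4 for interferon response (from 2), 1 to 5 for positional homeobox and limb genes (from 3). The cause was not tested.

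Among named genes and relations, 25594 of 26351 recomputed values kept direction and call, 680 lost the call, 60 gained it and 17 changed sign. Among lists in single comparisons the numbers were 8393 of 8730, 258, 72 and 7. The values that changed sign follow. With 1 FAT or PMFH array left out the ranges were IL24 PMFH vs other subtypes -0.151 to 2.182 (changed without PMFH replicate 1), IL24 MFS vs PMFH -2.333 to 0.000 (changed without PMFH replicate 1), the list interferon response PMFH vs FAT -0.658 to 0.857 (changed without PMFH replicate 2), the list proliferation PMFH vs other subtypes -0.005 to 0.662 (changed without PMFH replicate 2), the list interferon response PMFH vs other subtypes -1.014 to 0.501 (changed without PMFH replicate 3), the list hypoxia and glycolysis PMFH vs other subtypes -0.070 to 0.997 (changed without PMFH replicate 1). For probe sets without cross-hybridisation suffixes: EGFR DDLPS vs FAT 0.059, PTN DDLPS vs FAT -0.098, ME1 LMS vs FAT 0.048, FGFR2 LMS vs FAT -0.055, PTN LMS vs FAT -0.112, ME1 MFS vs FAT 0.042, EGFR MFS vs FAT 0.058, ME1 PMFH vs FAT 0.164, ME1 MRCLPS vs FAT 0.132, EGFR MRCLPS vs FAT 0.078, ME1 PLPS vs FAT 0.039, FGFR2 PLPS vs FAT -0.038, EGFR PLPS vs FAT 0.035, PTN DDLPS vs other subtypes -0.037, ME1 MRCLPS vs other subtypes 0.062, the list mesothelial PMFH vs FAT 0.12, the list myxoid matrix and hyaluronan DDLPS vs other subtypes -0.006. For skeletal muscle list covariate: the list skeletal muscle DDLPS vs other subtypes 0. The covariate is the skeletal muscle list itself, so its own value is 0 by construction. For the others the cause was not tested. Quantile normalization and median centring moved the share of higher calls by at most 10 percentage points. A pseudocount was not run, since the values are already log2. No paired analysis was possible because the replicate numbers only name arrays and pair no specimens. Low signals near the background compress differences, and genes under the filter were not tested.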

Other observations

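The genes of this first paragraph were picked after their values were seen. MRCLPS expressed several genes that had low signals in the other groups. GNAT3, a taste transduction G protein, had a level of 9.15 ± 0.69 (n = 20) in MRCLPS and group means of 4.78 to 4.89 in the other tumours and 4.80 in FAT. CD36, a fatty acid transporter whose gene lies near GNAT3 in gene order, had 12.41 ± 0.38 in MRCLPS and 11.63 ± 0.43 in FAT (n = 9), so FAT had high CD36 without high GNAT3. SIM1, a transcription factor of the developing hypothalamus, had 9.25 ± 0.73 in MRCLPS and 4.91 ± 0.31 in FAT, and TAC1 had 9.29 ± 2.16 and 4.32 ± 0.77.

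Since PEG3, DLK1, MEST and NNAT are imprinted and high in MRCLPS, a hypothesis was that imprinted genes are higher there as a group. Over 18 other imprinted genes the mean log2 difference from the other subtypes was 0.19 and the median -0.05, with camera p = 0.64 and p = 0.632 with an estimated correlation. PEG10 (2.48), NDN (2.08) and MAGEL2 (1.53) were called higher, while PHLDA2 (-0.92) and GRB10 (-0.79) were below 0. The test gave no evidence for a shift of the whole group.

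Each comparison was set against 100 splits of the same arrays, the real one included. In 16 of 18 comparisons only the real split (1 split) gave as many genes. That is a share of 1 in 100, the smallest that 100 splits can give. It bears on the number of called genes and not on single genes. The real count and the highest of the other splits were 109 and 1 for DDLPS vs other subtypes, 457 and 1 for LMS vs other subtypes, 108 and 1 for MFS vs other subtypes, 766 and 2 for MRCLPS vs other subtypes, 70 and 18 for PLPS vs other subtypes, 800 and 37 for DDLPS vs MRCLPS, 134 and 13 for DDLPS vs PLPS, 699 and 30 for MRCLPS vs PLPS, 73 and 6 for MFS vs PLPS, 125 and 10 for DDLPS vs MFS. For the subtypes against FAT the real counts were 796 to 1202 and the highest of the other splits 37 to 360. For PMFH vs other subtypes 3 splits gave as many (42 against a highest of 50), a share under 0.05 by a small margin, and the count was 27 without PMFH replicate 3. For MFS vs PMFH 21 splits did (13 against 43), so chance cannot be excluded there.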
